A study of Rattus norvegicus with 12 samples.

How the data were processed

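Total RNA of rat striatum was hybridised to Illumina arrays after biotin labelling, 1 colour per array, with 6 LID and 6 PD control samples, per the labels. The labels name the kit used for RNA extraction from lipid-rich tissue and a Bioanalyzer check of quality. The lesion used to make the rats parkinsonian, the side sampled, the sex, the vehicle, the chip position and the scan date are not given in the sources used here.

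The deposited values are intensities on a linear scale, already made comparable between arrays by the authors: the quartiles and the maximum of all arrays coincided (upper quartile 425.689 and maximum 22793 on each array, medians within 0.0867 of each other), which is what quantile normalization gives. The software and the background correction are not given in the sources used here. No value was below 36.5 and each probe reached at least 57.6 on some array, so dim probes had been left out by a step that is not stated. Detection p-values were not used here, so no probe could be called undetected.

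Starting from these intensities, the background was corrected with normexp (offset 50) and the arrays were quantile normalised and taken as log2 with limma 3.58.1 in R 4.3.3. A fold change is therefore on the log2(corrected value + offset) scale and understates the change of dim genes. Every probe was tested with lmFit and eBayes, with group as the only term, two-sided, and Benjamini-Hochberg adjustment over all 13375 probes with a threshold of 0.05. Residual degrees of freedom were 10 and 13.3 after moderation, and the median residual SD was 0.104 log2 units.

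Probes were named from GEO's platform annotation: 9434 had 1 symbol, 3941 had none and 0 had several. Of the named probes, 9415 were looked up by gene identifier in a table of the assembly GRCr8 and 0 symbols changed. No coordinates are given because no build is named for the array. Of the 1606 called probes, 343 had no symbol. A gene was represented by its probe with the highest mean. Among 205 genes with more than 1 probe, 0 had called probes in opposite directions and 28 had only some probes called.

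The 32 gene lists, the rule for naming genes and most alternative settings were fixed before the data were examined. The rule named the 10 largest rises and falls among called genes, 20 fixed genes whatever their values, and up to 3 called members of each list with the largest change. Of the 20 fixed genes 16 were measured and 7 passed the threshold. The other 4, Fosb, Homer1, Drd3 and Chat, had no named probe here. In all, 88 genes were named by the rule, and genes outside it are said to be chosen after their values were seen. Lists were tested with camera (preset correlation 0.01, lists of at least 5 measured genes, adjusted over 32 lists), with an estimated correlation and with fry as alternatives. The score of a list on an array is the mean of its members, each standardised over the 12 arrays. Scores were compared with exact two-sided permutation tests over all assignments of 6 arrays.

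The steps were tested on simulated data drawn from the real means and residual SDs, with 200 of 13375 probes changed in each of 10 runs. For LID against PD control, 61.0% of probes changed by 0.3 log2 units were recovered, 93.6% of those changed by 0.6 and 98.6% of those changed by 1, and 4.47% of calls were false. The simulation has no correlation between genes, so it does not test the preset correlation of camera. It also gives all arrays equal noise, while limma's array weights ran from 0.594 (PD control replicate 3) to 1.74 (LID replicate 5). The recovered and false shares therefore hold for independent genes on arrays of equal quality.

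Alternatives were another normalization (normexp without quantile normalization, or median centring), filters on dim probes, the replicate number as a block, array weights, other variance models, 1 probe per gene, an offset of 1, other list tests and each array left out in turn. The planned offset of 50 is the setting used. After the data were examined, log2 of the deposited values, a fit without PD control replicates 1, 3 and 6, and a fit with cortical and choroid plexus scores as covariates were added. No pair of arrays held identical values, and every array was used.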

Results

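Messenger RNA levels were measured in rat striatum on 12 one-colour Illumina arrays, 1 per sample. The labels describe 6 samples from parkinsonian rats given chronic levodopa (L-DOPA methyl ester at 25 mg/kg with benserazide, an inhibitor of peripheral decarboxylation, at 6.25 mg/kg) that had become dyskinetic, here called LID, and 6 from parkinsonian rats without levodopa, here called PD control. RNA was taken on day 8 after the chronic treatment. The comparison addresses what differs in the parkinsonian striatum between dyskinetic rats given levodopa and rats without it. No group was given levodopa without becoming dyskinetic, so effects of levodopa, of benserazide and of the involuntary movements cannot be told apart. The table held 13375 probes, of which 9434 carried a gene symbol, for 9218 genes. Deposited intensities ran from 36.5 to 22793, and the number of arrays limits the precision. Log2 values of any pair of arrays correlated across probes at 0.979 to 0.996. Whether each sample came from a separate animal is not stated, so p-values measure the spread between these 12 samples.

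Trh, which encodes the precursor of thyrotropin-releasing hormone, had the largest rise of all named genes and was 7.42-fold higher in LID (log2 difference 2.89 ± 0.46 SE, n = 6 per group, limma adjusted p = 0.0018). Pdyn, the dynorphin precursor of direct-pathway neurons, was 3.72-fold higher (1.90 ± 0.14, adjusted p = 1.1e-05), and Nmu, the neuromedin U gene, was 4.76-fold higher (2.25 ± 0.25). Timp1, an inhibitor of matrix metalloproteinases, rose 6.50-fold (2.70 ± 0.32), and the receptor genes Sstr2 (somatostatin) and Hcrtr1 (orexin) rose 3.53-fold and 2.79-fold. Arhgap25, Inhba, Dmkn and Tgfb1 completed the 10 largest rises, at log2 differences of 1.39, 1.38, 1.31 and 1.26, and in each of these 10 genes every LID array lay above every PD control array.

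The falls were smaller. Sgk1, a kinase gene induced by glucocorticoids, was 2.23-fold higher in PD control than in LID (log2 difference -1.16 ± 0.14, adjusted p = 0.00034). Fn3k, which encodes fructosamine-3-kinase, fell by 0.84 on the log2 scale, Zfp593 by 0.77 and Opalin, a gene of myelinating oligodendrocytes, by 0.75. Matk, Filip1, Dleu7, Pnma2 and Map2k6 fell by 0.74, 0.72, 0.67, 0.67 and 0.65. Cdk14 fell by 0.76, a call that was lost in 8 of the 12 fits that left out 1 array.

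Across all probes, 1606 passed the threshold (limma, Benjamini-Hochberg adjusted p under 0.05), 865 higher and 741 lower in LID, which is 12.0% of those tested. By the probe that stood for each gene, 688 genes were higher and 556 lower. Most changes were modest: the median absolute log2 difference of called probes was 0.28, 101 called probes were at least 1.5-fold higher and 26 at least 1.5-fold lower. The groups did not overlap at 818 probes, 6.12% of the table, where chance gives 0.217%. Without PD control replicates 1, 3 and 6, whose marker scores for other brain tissue stood apart, 1059 probes passed, of which 816 were among the 1606. Of the 79 named genes past the threshold with all arrays, 28 were no longer past it in that fit, which has 3 arrays fewer. Of these 28, 16 kept at least 80% of their log2 difference. Mmp9 (0.52 with all arrays and 0.51 without the 3), Rpl3 (-0.20 and -0.20), S100a8 (0.36 and 0.34), Pde4b (0.45 and 0.41), Gria2 (-0.24 and -0.22) and Cryab (0.68 and 0.57) were among the 16. Pnma2 (-0.67 and -0.53), Psmb10 (0.32 and 0.22), Mlc1 (0.35 and 0.22) and Cdk14 (-0.76 and -0.41) kept less.

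Markers of the direct pathway, the striatal output neurons that carry the D1 dopamine receptor, were higher in LID as a list by limma's camera test (median log2 difference 0.19, adjusted p = 0.0049 over 32 lists; adjusted p = 0.39 with an estimated correlation). Of 9 measured, 4 rose and none fell: Pdyn, Tac1 (the substance P precursor, 2.38-fold, 1.25 ± 0.17), Drd1 (the D1 receptor, 1.48-fold, 0.57 ± 0.11) and Ebf1 (0.40 ± 0.10, chosen after its value was seen). Of 7 measured markers of the indirect pathway, the neurons that carry the D2 receptor, 1 rose (Necab1, 0.31 ± 0.09, lost in 6 of 12 fits without 1 array). Penk (0.15 ± 0.11), Drd2 (0.13 ± 0.11) and Adora2a (0.01 ± 0.13) did not pass, with 95% intervals of -0.077 to 0.383, -0.104 to 0.368 and -0.279 to 0.299.

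**Figure D1:**
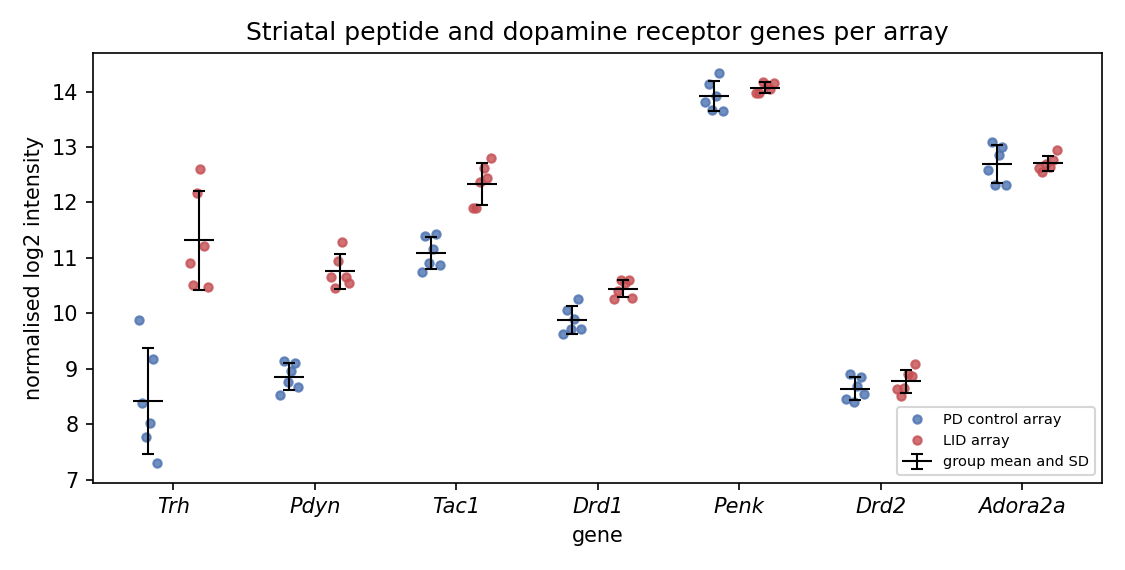
Normalised log2 intensity of 7 genes in each array, with the mean and SD of the 6 PD control and 6 LID arrays. Every LID array lay above every PD control array for Trh, Pdyn and Tac1, while the groups overlapped for Drd1, Penk, Drd2 and Adora2a.

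The indirect-pathway list was not past the threshold (median 0.021, or 0.0087 without LID replicate 5 and 0.090 without PD control replicate 2, adjusted p = 0.56). Its members Grik3 and Plxdc1, named after their values were seen, were dim in both groups and could show little change. Their mean log2 values were 6.21 and 6.11 in PD control and 6.23 and 6.11 in LID. The list's median was the value of Grik3. The mean of the direct markers minus that of the indirect markers was 0.46 higher in LID (exact two-sided permutation p = 0.00216, the smallest that 6 against 6 arrays can give). Without Pdyn and Tac1 the difference was 0.15 (exact permutation p = 0.0736), so it rests largely on these 2 genes. Without the 3 control arrays named above, the direct-pathway list's median was 0.14 (adjusted p = 0.061) and the difference of Drd1 was 0.37 (adjusted p = 0.051).

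The wider list of striatal projection neuron genes had 5 members higher and 1 lower among 24 measured. Strn (0.66 ± 0.15), Ptpn5, the striatum-enriched phosphatase (0.50 ± 0.10), and Adcy5, the main striatal adenylyl cyclase (0.47 ± 0.11), rose, while Ppp1r1b, which encodes DARPP-32, differed by 0.07 ± 0.11 and did not pass. The list's median was 0.14 (camera adjusted p = 0.0088; adjusted p = 0.74 with an estimated correlation). PD control replicate 1 decided this call: without it the median was 0.052 and the adjusted p 0.078. Without all 3 control arrays the median was -0.027 (adjusted p = 0.90), and Strn (0.41), Ptpn5 (0.41) and Adcy5 (0.26) were no longer past the threshold. These 3 arrays had the lowest scores of PD control for this list, so leaving them out lowers its difference whatever the cause.

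Of 23 measured neuropeptide and opioid genes, 7 were higher, 1 was lower and 15 did not pass (median 0.14, camera adjusted p = 0.0083; adjusted p = 0.35 with an estimated correlation). The median was 0.074 without PD control replicate 1 and 0.070 without replicate 5, with adjusted p of 0.019 and 0.023. Beside Trh, Pdyn and Tac1 the higher genes included Tac3, which encodes the neurokinin B precursor (0.83 ± 0.16). Scg2 (secretogranin II, 1.23 ± 0.14) and Nts (neurotensin, 0.94 ± 0.19) also rose, and Oprl1, the nociceptin receptor gene, fell by 0.37. Scg2, Nts and Oprl1 were chosen after their values were seen. Th, which encodes the rate-limiting enzyme of dopamine synthesis, was 1.71-fold higher (0.78 ± 0.17, adjusted p = 0.0090) from a dim signal in PD control (mean log2 5.98). It was 1 of 2 genes of catecholamine handling that rose among 9 measured, with Sv2c (0.58 ± 0.07), in a list that did not pass (median 0.11, or 0.065 without LID replicate 3, adjusted p = 0.28). Without the 3 control arrays the difference of Th was 0.79, no smaller than with them, at an adjusted p of 0.059.

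Immediate early and activity-regulated genes were higher as a list, with 10 of 33 measured members up and 1 down (median 0.19, camera adjusted p = 0.00036; adjusted p = 0.72 with an estimated correlation). Members that rose included Inhba, a subunit of activins (1.38 ± 0.17), Klf10 (1.05 ± 0.14), Nptx2, a pentraxin that clusters AMPA receptors (1.01 ± 0.22), and the prostaglandin synthase gene Ptgs2 (0.77 ± 0.11). The transcription factor genes of the list were divided. Beside Klf10, Nr4a3 (0.71 ± 0.21, adjusted p = 0.045), Crem (0.79 ± 0.09, adjusted p = 0.00029) and Nfil3 (0.61 ± 0.12, adjusted p = 0.0054) rose, all 3 chosen after their values were seen. Fos differed by 0.30 ± 0.20, Egr1 by 0.37 ± 0.20 and Nr4a1 by -0.03 ± 0.05, and these did not pass, nor did Jun, Junb, Egr2 and Egr4. Nr4a1 was dim in both groups (mean log2 6.14 in PD control and 6.10 in LID), so it could show little change. Fosb had no named probe. Arc, which encodes a synaptic protein, differed by 0.51 ± 0.24 and did not pass. In PD control replicate 6 the list's score was 0.66, against -0.72 to -0.30 in the other PD control arrays. Without that array alone Fos (0.48, adjusted p = 0.028), Egr1 (0.56, adjusted p = 0.016) and Arc (0.71, adjusted p = 0.027) passed. Other arrays moved them down: Fos was 0.17 without PD control replicate 5, Egr1 0.26 without PD control replicate 1 and Arc 0.42 without LID replicate 6. Without replicates 1, 3 and 6 of PD control, Fos (0.59, adjusted p = 0.023) and Egr1 (0.55, adjusted p = 0.022) passed, and Nptx2 kept its difference (0.99) but not its call (adjusted p = 0.064).

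Astrocyte markers were higher in LID as a list by camera. Of 15 measured, 5 rose, none fell and 10 did not pass (median 0.21, camera adjusted p = 0.0064; adjusted p = 0.64 with an estimated correlation), and those that rose included the connexin gene Gjb6 (0.68 ± 0.10), the glutamate transporter gene Slc1a2 (0.34 ± 0.07) and Mlc1 (0.35 ± 0.09). The astrocyte score per array differed by 0.725 SD units (exact permutation p = 0.0173) and did not pass after adjustment over 15 scores (0.0866). Of 11 genes of reactive astrocytes 4 rose over all probes tested and 8 adjusted over the list alone (median 0.47, camera adjusted p = 8.0e-06; adjusted p = 0.064 with an estimated correlation). Timp1, Hspb1 (0.65 ± 0.16) and Lcn2 (0.55 ± 0.10) led this list. Gfap, the astrocyte intermediate filament gene, differed by 0.47 ± 0.17 and missed the threshold (adjusted p = 0.085), which it passed without PD control replicate 2 (0.56, adjusted p = 0.045).

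Genes of angiogenesis and the vascular barrier were higher as a list, with 7 of 20 measured up and none down (median 0.18, camera adjusted p = 0.0020; adjusted p = 0.064 with an estimated correlation). Mmp14 and Mmp9, which encode matrix metalloproteinases, rose by 0.79 ± 0.14 and 0.52 ± 0.12. Angpt2, a destabiliser of vessels, rose by 0.53 ± 0.04 from a dim signal. The endothelial list, with 2 members higher and 2 lower of 16, did not pass (median 0.064, or 0.042 without PD control replicate 4, adjusted p = 0.096): Egfl7 rose by 0.94 ± 0.16 and Itm2a fell by 0.56. It passed without PD control replicate 6 (median 0.11, adjusted p = 0.0099).

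Heat-shock and protein-folding genes were higher as a list, with 7 of 16 measured up and none down (median 0.20, camera adjusted p = 4.1e-06; adjusted p = 0.064 with an estimated correlation). Hspa5, the chaperone BiP of the endoplasmic reticulum, had the smallest p of all probes (1.74-fold, 0.80 ± 0.05, adjusted p = 6.9e-06). Cryab (0.68 ± 0.16) and Hspb1, both small heat-shock proteins, also rose. The proteasome list had 5 of 36 genes higher and 1 lower and did not pass (median 0.032, adjusted p = 0.089).

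Lists lower in LID were those of oligodendrocytes and of cytosolic ribosomal proteins. Of 19 oligodendrocyte genes, Opalin and Cnp, an enzyme of myelin (-0.45 ± 0.10), fell and none rose (median -0.14, camera adjusted p = 0.027; adjusted p = 0.81 with an estimated correlation). Without PD control replicate 3 the median was -0.21, and without replicate 1 it was -0.088. The call was lost in each fit without PD control replicate 1, 2, 4 or 5 or without LID replicate 2, 3 or 4 (adjusted p 0.052 to 0.11). Of 61 ribosomal protein genes 6 fell and none rose, by small amounts such as 0.24 for Rpl13a and 0.20 for Rpl3 (median -0.076, camera adjusted p = 0.0042; adjusted p = 0.74 with an estimated correlation). Mbp, the myelin basic protein gene, chosen after its value was seen, differed by 0.11 and did not pass.

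Genes that respond to glucocorticoids moved in both directions. Among 16 measured, 5 rose and 4 fell: Fkbp5, a cochaperone of the glucocorticoid receptor (0.79 ± 0.07), and Sult1a1 (0.65 ± 0.12) were higher, while Sgk1 was lower and Nfkbia, an inhibitor of NF-kB (-0.47 ± 0.07), fell. The list did not pass (adjusted p = 0.88), and its median (-0.076, or -0.044 without LID replicate 5) and mean (-0.029) were negative while camera's direction was up. Genes of GABA signalling had 5 members higher and 1 lower of 14 (median 0.023, or -0.023 without LID replicate 1 and 0.074 without PD control replicate 4, adjusted p = 0.31), with Gad2 (0.49 ± 0.11), Abat (0.39 ± 0.08) and Gad1 (0.37 ± 0.09) higher. Without the 3 control arrays Gad1 differed by 0.21 and did not pass (adjusted p = 0.15).

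Other signalling lists were not past the threshold. Dopamine receptor, cAMP and ERK genes had 5 members higher and 3 lower of 27 (median 0.075, or 0.010 without PD control replicate 1 and 0.11 without replicate 2, adjusted p = 0.28), with the phosphodiesterase gene Pde4b at 0.45 ± 0.10. Glutamate receptor and postsynaptic genes had Dlg1 higher (0.47 ± 0.08) and Gria2 lower (-0.24 ± 0.06) of 26 (median 0.0049, or -0.043 without PD control replicate 1 and 0.029 without LID replicate 1, adjusted p = 0.85). Potassium and calcium channel genes had 5 higher and 3 lower of 23 (median 0.014, or -0.010 without LID replicate 4 and 0.058 without PD control replicate 5, adjusted p = 0.56), with Cacnb4 at 0.40 ± 0.06 and Kcnd3 at -0.52 ± 0.13. Synaptic vesicle genes had Syt4 higher and Sv2a lower of 20 (median -0.060, or -0.014 without PD control replicate 2, adjusted p = 0.56). Oxidative phosphorylation genes had Cox8a higher and Ndufs7 lower of 56 (median -0.018, or -0.039 without PD control replicate 3 and -0.0040 without replicate 1, adjusted p = 0.52), and oxidative stress genes had Gpx4 and Gstp1 lower of 19 (median -0.0069, or -0.018 without PD control replicate 6 and 0.041 without LID replicate 4, mean 0.0043, adjusted p = 0.91).

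**Figure D2:**
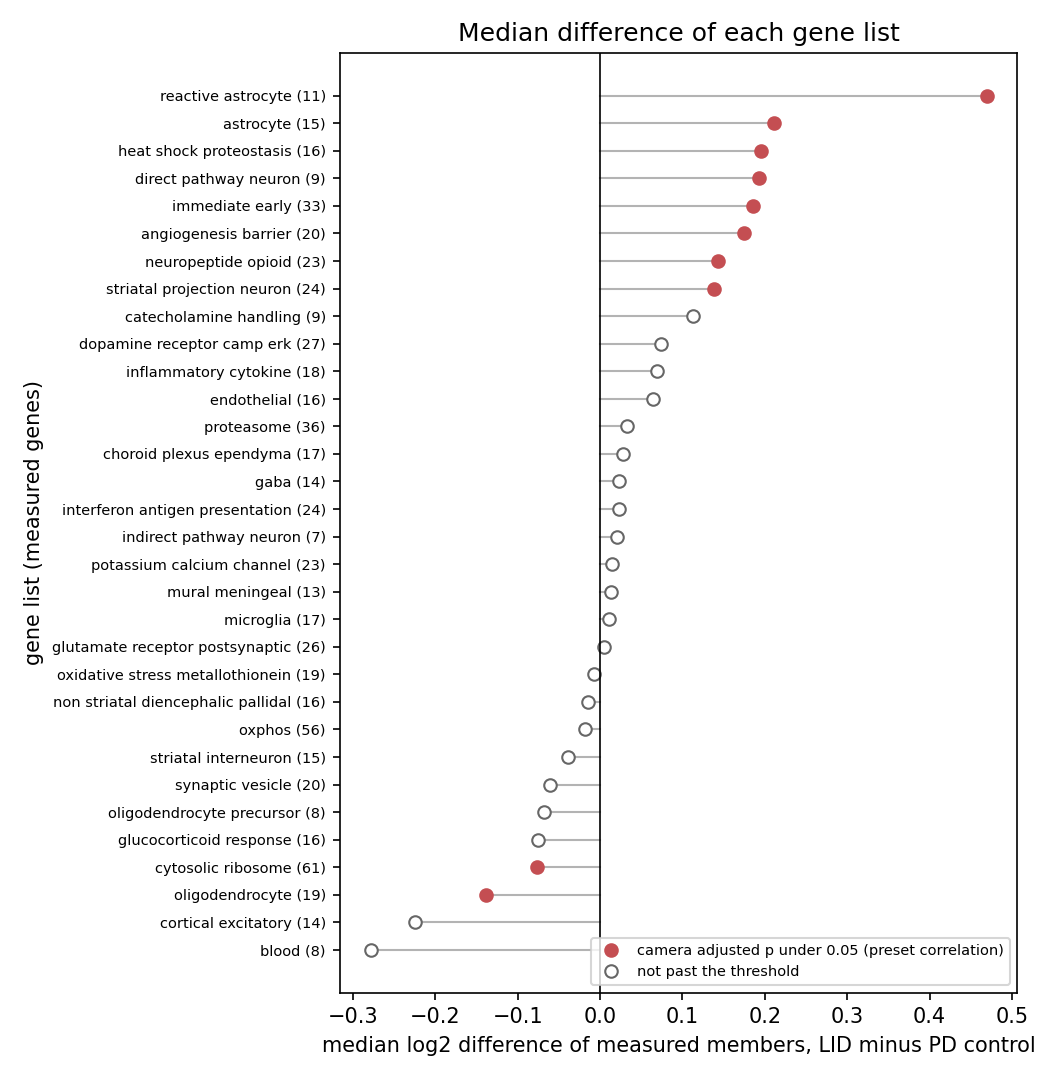
Median log2 difference (LID minus PD control) of the measured members of each of 32 gene lists, with the number measured in parentheses and filled points for camera adjusted p under 0.05 with a preset correlation. The 8 filled lists on the right include reactive astrocytes at 0.47, and the 2 on the left are oligodendrocytes at -0.14 and ribosomal proteins at -0.076.

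No immune list passed the threshold. Interferon and antigen presentation genes had Irf1 (0.29 ± 0.05) and Psmb10 (0.32 ± 0.08) higher of 24 (median 0.023, or 0.010 without PD control replicate 6 and 0.040 without LID replicate 3, adjusted p = 0.43). Inflammatory genes had 3 higher, with Tgfb1 first, and Nfkbia lower of 18 (median 0.069, or 0.027 without LID replicate 2, adjusted p = 0.14). The microglial list had only Aif1, which encodes IBA1, past the threshold (-0.41 ± 0.08) of 17 (median 0.011, or -0.028 without PD control replicate 3 and 0.027 without replicate 2, mean -0.010, camera direction down, adjusted p = 0.85).

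Markers of other cells and neighbouring tissue were compared in the same way. Cortical excitatory genes had Emx2 higher (0.43 ± 0.07) and Etv1 lower (-0.24 ± 0.05) of 14, with a median of -0.22 (adjusted p = 0.16), or -0.10 without PD control replicate 3. Choroid plexus and ependymal genes had none of 17 past the threshold (median 0.028, or -0.072 without LID replicate 1 and 0.28 without PD control replicate 1, adjusted p = 0.88), nor had diencephalic and pallidal genes (0 of 16, median -0.015, or -0.043 without PD control replicate 6 and 0.033 without replicate 1, adjusted p = 0.98) or oligodendrocyte precursors (0 of 8, median -0.069, or -0.14 without PD control replicate 2 and -0.038 without replicate 4, adjusted p = 0.57). The interneuron list had Tac3 higher and Lhx6 (-0.27 ± 0.07) lower of 15 (median -0.039, or -0.11 without PD control replicate 5, adjusted p = 0.56). Tac3 is also a member of the neuropeptide list, and its rise in whole striatum was not assigned to a cell type. Mural and meningeal genes had Vtn lower (-0.36 ± 0.08) of 13 (median 0.013, or -0.021 without LID replicate 2 and 0.030 without PD control replicate 5, mean -0.0071, camera direction down, adjusted p = 0.88). Blood genes had S100a8 higher and Pf4 and Ahsp lower of 8 (median -0.28, adjusted p = 0.16).

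Scores of these markers per array set 3 PD control arrays apart. PD control replicate 1 had a choroid plexus score of 1.94 SD units, against -0.876 to 0.0417 in the other PD control arrays, and a diencephalic score of 1.48. Among LID arrays the choroid plexus score was highest in replicate 1 (0.979) and replicate 2 (0.559). PD control replicates 3 and 6 had cortical scores of 1.35 and 1.07, and the direct-pathway scores of these 3 arrays were -1.005, -0.515 and -0.891, against -0.105 to 0.115 in the other PD control arrays. Of 15 marker scores compared by exact permutation tests, those of reactive astrocytes (LID minus PD control 1.31, exact p = 0.00216, adjusted 0.0325) and direct-pathway neurons (0.809, exact p = 0.00433, adjusted 0.0325) differed between the groups. The cortical score differed by -0.483 (exact p = 0.245) and the choroid plexus score by 0.0542 (exact p = 0.933).

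**Figure D3:**
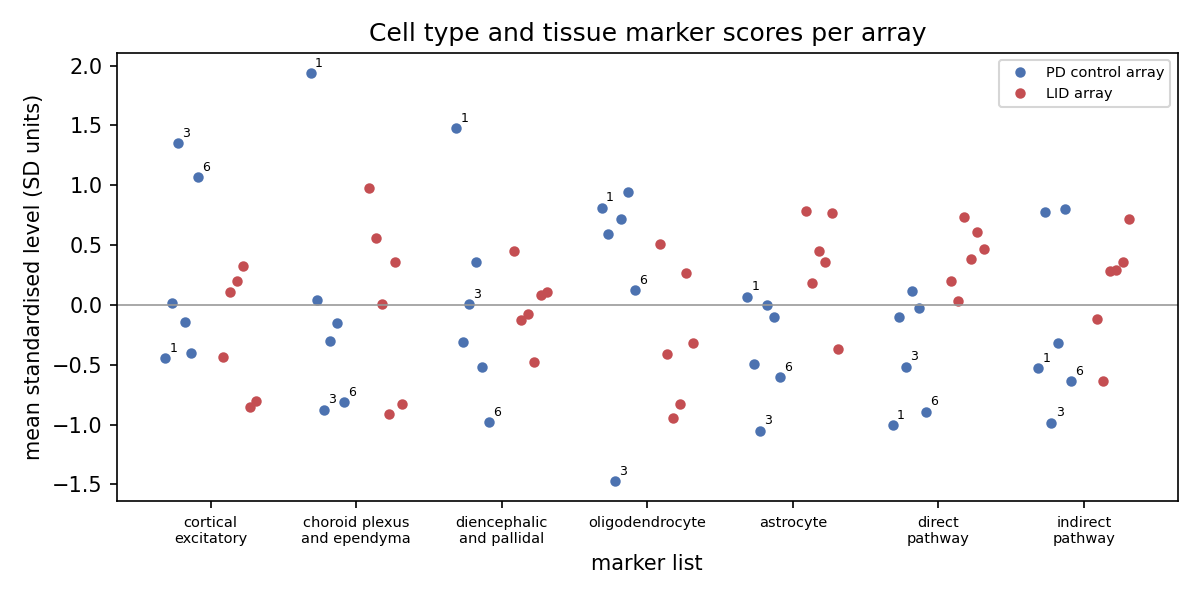
Mean standardised level of 7 marker lists in each of the 6 PD control and 6 LID arrays, in SD units, with PD control replicates 1, 3 and 6 numbered. Replicate 1 stands highest for choroid plexus (1.94), and replicates 3 and 6 stand highest for cortical genes (1.35 and 1.07).

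In total 10 of the 32 lists passed with camera's preset correlation of 0.01, 8 up and 2 down, and 0 passed with a correlation estimated from the data, while limma's fry test called 8, none of them down. Of these 8, 7 were among the 10. The projection neuron (adjusted p = 0.27), oligodendrocyte (0.37) and ribosomal (0.15) lists did not pass by fry, and the proteasome list did (0.048). Adjusted over the list alone, 13 immediate early genes were up and 2 down, 10 angiogenesis genes up and 1 down, 8 heat-shock genes up, 6 astrocyte genes up, 4 direct-pathway genes up and 1 down, 6 endothelial genes up and 2 down, 6 GABA genes up and 1 down, and 6 channel genes up and 4 down. Gpx4, Gstp1, Cox8a and Sv2a did not pass when adjusted over their list alone. In the 10 lists the estimated correlation between members ran from 0.017 (angiogenesis) to 0.62 (oligodendrocytes). At least 10 lists passed with the preset correlation in 26 of 100 splits of the 12 arrays into 6 and 6, the real split included. The median of the other splits was 8 lists, so the preset correlation also called lists in groupings other than the real one.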

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

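The test with marker scores as covariates, the direct against indirect test and the fits without 3 control arrays were chosen only after the result was seen; the counts over other splits were planned before the splits were computed. A Dixon test of the highest or lowest array of each group of 6 was run on 240 groups of values, and 11 exceeded the 95% critical value for 6 samples, where chance gives about 1 in 20, or 12.

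In PD control replicate 6, Arc was at a log2 intensity of 9.34 (others 7.93 to 8.34), Klf10 at 7.54 (others 6.59 to 6.93) and the immediate early score at 0.663. PD control replicate 3 had Cnp at 11.9 (others 12.3 to 12.5) and an oligodendrocyte score of -1.47. PD control replicate 2 had Ptpn5 at 11.3 (others 10.9 to 11.0) and Abcg2 at 6.71 (others 7.32 to 7.64). PD control replicate 1 had a choroid plexus score of 1.94. LID replicate 2 had S100a8 at 6.54 (others 5.94 to 6.16) and an inflammatory score of 1.34, and LID replicate 6 had a synaptic vesicle score of -0.749.

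The number of probes past the threshold could be due to chance or to cortex or choroid plexus tissue in some control samples. Of 100 splits of the 12 arrays, only the real one gave as many as 1606 probes. The highest other gave 47, which argues against chance. These 100 were drawn from 462 possible splits, so the smallest share the count could give was 1 in 100. With the cortical and choroid plexus scores as covariates 1319 of the 1606 probes (82.1%) stayed past the threshold, among 1766 called in that fit. That argues against tissue captured by these 2 scores as the whole cause. Adjustment could remove little, since the scores differed by -0.483 (exact permutation p = 0.245) and 0.0542 (exact permutation p = 0.933) between the groups. The diencephalic score, 1.48 in PD control replicate 1, was not among the covariates. Of the 79 named genes past the threshold, 9 lost their call with the covariates. Without the 3 control arrays, which also leaves fewer arrays, 816 of the 1606 (50.8%) stayed, so cortex or choroid plexus tissue as part of the cause stays open. For the number of lists, 26 of 100 splits, the real one included, gave at least the real 10. The other splits had a median of 8 and a highest of 15, so chance cannot be excluded. A treatment effect on the probes stays open as a hypothesis, and batches could not be tested because the labels give none.

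The projection neuron genes divide under the same explanation. Less striatum in control samples would lift direct and indirect markers alike, yet the direct minus indirect difference was 0.46 (exact permutation p = 0.00216). It was also 0.46 without the 3 control arrays (exact permutation p = 0.0119, the smallest possible there). The indirect mean includes the dim Grik3 and Plxdc1, and Upb1, which differed by -0.46 and did not pass. The brighter Penk (0.15), Drd2 (0.13) and Adora2a (0.01) differed less than Pdyn (1.90) and Tac1 (1.25). That argues against less striatum as the whole cause for Pdyn and Tac1, the genes that carry most of that difference. The wider projection neuron list lost its call, with a median of -0.027 without the 3 arrays and 0.068 with the scores as covariates (adjusted p = 0.18), as uneven dissection of the control samples would give. The list's members did not all rise: of 24 measured, 20 had a positive sign, but 5 were higher, 1 lower and 18 not past the threshold. Rgs9 (-0.02) and Pde10a (0.05), chosen after their values were seen, were among the 18. Dissection as a cause of the higher projection neuron list stays open. It also stays open for Drd1, at 0.57 with all arrays and 0.37 without the 3.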

How the results depend on the processing

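The fits with log2 of the deposited values, with marker scores as covariates and without PD control replicates 1, 3 and 6 were chosen after the data were seen. The number of probes past the threshold, 1606, ranged from 1268 to 1798 over the other alternatives run on all 12 arrays and from 1112 (without LID replicate 4) to 1557 (without LID replicate 2) with 1 array left out. Without PD control replicates 1, 3 and 6 it was 1059 (524 higher, 535 lower), with 3 control arrays fewer. The number of lists was 8 to 11 in all other settings, and 0 with camera's correlation estimated from the data, a test in which both the correlation and the degrees of freedom (10, those of the arrays) differ; which of these ended the calls was not tested. Of 79 named genes past the threshold, 63 kept their call without each array in turn and 16 lost it at least once. The number of arrays whose removal ended a call was, by gene: Gstp1 11, Sv2a 10, Abcg2 9, Ahsp 9, Gpx4 9, Psma5 9, Cdk14 8, Cox8a 7, Kcnc1 6, Necab1 6, Pf4 6, Lhx6 4, Syt4 3, Kcnd3 2, Mlc1 2, Rpl22l1 2. The replicate block gave 1332 probes and 10 lists, and 6 of the 79 named genes lost their call. The sample titles number the arrays consecutively, PD control first and LID after, so they name no pairs and group follows array number completely. Replicate numbers here count the arrays within each group. They did not pair the samples: 2 of 6 same-numbered pairs deviated together with a correlation over 0.1 (range -0.292 to 0.482). In all, 3 arrays correlated best with their own number.

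Signs (for lists, the direction of camera) changed in 54 cases, none of which involved a result past the threshold in either setting; the cause was not tested. Without the 3 control arrays the values were Adora2a -0.28, Ppp1r1b -0.086, Penk -0.060 and Drd2 -0.045, and the list medians were -0.045 for indirect-pathway and for dopamine signalling genes, 0.025 for synaptic vesicle, 0.039 for mural, 0.017 for diencephalic and 0.015 for oxidative stress genes. With the scores as covariates Adora2a was -0.17, Ppp1r1b -0.022 and Drd2 -0.0033, and medians were -0.0033 for indirect-pathway, 0.012 for synaptic vesicle, 0.027 for cortical and -0.019 for oxidative stress genes. Among brighter probes medians were -0.028 for interneuron, -0.12 for catecholamine and -0.16 for glucocorticoid genes. The replicate block gave -0.076 for glucocorticoid genes, array weights gave -0.035 for diencephalic genes and -0.091 for Adora2a, and log2 of the deposited values gave -0.016 for diencephalic genes. With 1 array left out, Adora2a ranged from -0.067 to 0.090, and the medians ranged from -0.072 to 0.28 (choroid plexus), -0.11 to -0.044 (glucocorticoid), -0.043 to 0.029 (glutamate), -0.028 to 0.027 (microglia), -0.021 to 0.030 (mural), -0.043 to 0.033 (diencephalic), -0.018 to 0.041 (oxidative stress) and -0.079 to -0.014 (synaptic vesicle). Signal over background limits dim genes, since no detection p was used. Examples are Th, Angpt2, Lcn2, S100a8, Hcrtr1, Tgfb1, Sv2c, Nr4a1, Grik3 and Plxdc1, with mean log2 values of 5.79 to 6.33 in PD control.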

Other observations

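Genes in this part were chosen after their values were seen, except the heat-shock factor targets and Usp2, Wee1 and Clock; the time-of-day test was chosen after the result, and the temperature test before it. Of 13 chaperone genes of the endoplasmic reticulum 10 were higher and 0 lower in LID, with a median log2 difference of 0.42, and this choice of genes is not independent evidence of a group change. Creld2 (0.59 ± 0.07), Pdia3 (0.55 ± 0.08), Dnajc3 (0.52 ± 0.08), Hsp90b1 (0.46 ± 0.06) and Calr (0.45 ± 0.04) rose with Hspa5, and Xbp1, a transcription factor of the unfolded protein response, rose by 0.42. Ddit3 (0.23 ± 0.12) and Atf4 (-0.06 ± 0.08), markers of its stress arm, did not pass, and the oxidase gene Ero1a fell by 0.45.

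Other single genes were higher, with no test of a group: the activin receptor gene Acvr1 (0.54 ± 0.06), Pmepa1 (0.86 ± 0.11), fibronectin (Fn1, 0.82 ± 0.12), Col5a2 (0.60 ± 0.10) and lysyl oxidase (Lox, 0.51 ± 0.07). Htr1b, a serotonin receptor gene, was 2.06-fold higher (1.04 ± 0.12).

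Clock genes moved in opposite directions. Cry1 (0.78 ± 0.07) and Nfil3 (0.61 ± 0.12) were higher, Nr1d1 (-0.62 ± 0.08), Per1 (-0.59 ± 0.10), Usp2 (-0.27 ± 0.07) and Dbp (-0.26 ± 0.05) were lower, and Bmal1 (0.03 ± 0.05), Npas2 (0.06 ± 0.08) and Per2 (0.01 ± 0.12) did not pass. Collection at another time of day may give this pattern, and the bound set against it was any gene that peaks with Nr1d1 and Dbp moving up. That bound was met by 1 gene, Wee1 (0.23 ± 0.05), but a bound on 1 gene was wrong for a set, and the 2 genes of that phase chosen without seeing their values went opposite ways, Usp2 down and Wee1 up. Collection times are not given in the sources used here, so time of day and treatment cannot be told apart for these genes.

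Cirbp (-0.56 ± 0.07) and Rbm3 (-0.53 ± 0.09), RNA-binding proteins induced by mild cold, were lower in LID while Hspb1, Cryab and Hspa5 were higher. Hspa5 rose together with other chaperones of the endoplasmic reticulum, so its rise is not counted for temperature. A hypothesis is that brain temperature was higher in LID, which would lift targets of heat-shock factor 1 beyond Hspb1 and Cryab. Of 12 measured targets whose values had not been seen, 3 rose (Chordc1 0.42 ± 0.08, Stip1 0.28 ± 0.05, Hspa4l 0.28 ± 0.07) and 0 fell. Their median was 0.042, under the bound of 0.1 set for the hypothesis, while camera gave p = 0.0385 for a rise (p = 0.197 with an estimated correlation), so the test did not decide. Temperature and treatment cannot be told apart here.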
